A study of Mus musculus with 10 samples.

How the data were processed

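The deposited table of intensities was used as it stood. The software that computed the intensities was not given in the sources used here. On each array the mean after removal of 2% of values at either end was 299.3 to 300.1 (largest difference 0.254%), so the values were taken as scaled by the authors to a target of about 300 and were not scaled again. The table held 12488 probe sets, of which 66 were controls; 10855 had 1 gene symbol, 396 several and 1237 none. No symbol changed when it was updated through its Entrez identifier, and 10839 probe sets matched the gene table of GRCm38.p6. No column belonged to a sample outside the 10 arrays.

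Values below the 20th percentile of all values, 16, were raised to it, which affected 15.4% to 24.2% of the values of an array, and log2 was taken. Control probe sets were removed, and a probe set was tested if it lay above the median of the array on at least 2 arrays, which left 7172 probe sets, 6447 of them with 1 symbol, from 5476 genes of which 841 had more than 1 tested probe set. Folds are 2 to the power of the mean log2 difference and so can differ from the ratio of the mean intensities beside them. A fold is given as at least that size only where every array of the dimmer group lay at the floor; where some did, their number is given. Differences, standard errors and p-values came from limma 3.58.1 in R 4.3.3 with 1 mean per group over the 10 arrays and eBayes (7 residual and 3.17 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the tested probe sets of a comparison, with adjusted p under 0.05 as the criterion. Group values are means ± SD of intensity and log2 differences are ± standard error. The groups, comparisons, 24 gene lists and alternatives were fixed before the data were examined, and 6 further alternatives that separate batches were chosen after seeing the data: fluidics run as a block, lot 1 only, day 1 only, run 1 only, run 2 only, and day as a block without tumour 6.

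Genes were named by a fixed rule. Per comparison, among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of the groups, the 10 genes with the largest rise and the 10 with the largest fall were named, with 1 probe set per gene, the one with the highest mean over all arrays. Where fewer than 5 passed in a direction, the 5 genes with the smallest unadjusted p in that direction were named as values only. From each list up to 4 measured members with the smallest unadjusted p were eligible, and Ikzf1, Notch1, Notch3, Hes1, Dtx1, Ptcra, Il2ra and Myc were always read. Of 23 called genes with several probe sets between tumours and wild-type thymocytes, 5 had a probe set of opposite sign (C1qb, Col1a2, Grn, Otub1 and S100a10), and of 18 against IkL/L thymocytes 3 did (C1qb, Col1a2 and Ifnar2).

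Each gene list was tested with camera on 1 probe set per gene, with a preset correlation of 0.01 between genes and, as an alternative, with the correlation estimated from the data, and adjusted over the 24 lists. With the estimated correlation no list was called in any comparison. Adjustment over the list alone used the Benjamini-Hochberg method within its members. Chip lot, hybridization day and fluidics module were read from the scanner records, and hybridizations within 10 minutes of each other were taken as 1 fluidics run: run 1 held tumours 4 and 6 and a wild-type array, run 2 the other wild-type array and both IkL/L arrays, run 3 tumours 1, 2 and 5, and run 4 tumour 3. No run held both tumours and IkL/L arrays, so with run as a block that comparison passes through a single wild-type array in each of runs 1 and 2. No paired analysis was possible because replicate numbers of wild-type and IkL/L thymocytes follow only the order of deposition.

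Shifts per chromosome were medians over 5467 placed genes of the log2 difference between an array and the mean of the thymocyte arrays, relative to the array's own median, and were compared by permutation with 10000 random gene lists of like size and intensity. Overlap of comparisons was set beside 100 simulated data sets without genotype effects, in which each group kept its own spread; a spread shared by all groups was used at first, and the change was made after that result was seen.

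The procedure was run on simulated arrays with the spread of the real ones and 200 altered probe sets. Between tumours and wild-type thymocytes 31.3%, 77.6% and 90.9% of 2-fold, 4-fold and 8-fold changes were called, with 18 of 6972 unaltered probe sets called. Between tumours and IkL/L thymocytes 43.3%, 74.6% and 87.9% were called, with 12 unaltered ones, and between the thymocyte genotypes 16.4%, 67.2% and 89.4%, with 13. None was called in the wrong direction, and 3 of 3 altered lists and 0 of 21 unaltered lists were called in each comparison. The simulated genes varied independently, whereas the correlation estimated within the real lists reached 0.415 (double-positive genes). The list result therefore does not show how often lists of correlated genes are called without cause. Between tumours and wild-type thymocytes the 18 false calls stood beside 21, 52 and 60 true ones.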

Results

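Messenger RNA levels were measured in total RNA from 10 mouse samples on MG_U74Av2 oligonucleotide arrays with 12488 probe sets. Ikaros, the zinc-finger transcription factor encoded by Ikzf1, is required for normal lymphocyte development. The samples were 6 advanced thymic tumours from mice homozygous for a hypomorphic Ikaros mutation (IkL/L), 2 preparations of unfractionated thymocytes from 3-week-old wild-type mice and 2 such preparations from 3-week-old IkL/L mice. No age was given for the tumour-bearing mice, so differences between tumours and thymocytes could include an effect of age. The deposited intensities had trimmed means of 299.3 to 300.1 and medians of 79.8 (tumour 4) to 113 (tumour 6), and no 2 arrays held identical values. The labels did not state that the tumours came from separate mice, so p-values of single probe sets measure only the spread between arrays. The 2 arrays in each thymocyte group limit the precision. P-values of gene lists also depend on the spread between genes. Those of chromosomes compare genes within 1 array and measure no spread between arrays. The scanner records placed tumour 6 and all 4 thymocyte samples on chip lot 1 and tumours 1 to 5 on lot 2. Tumours 4 and 6 were hybridized with the thymocytes on day 1, tumours 1, 2 and 5 on day 2 and tumour 3 on day 3. Lot was thus separable from the tumour state only through tumour 6, and day only through tumours 4 and 6. With lot as a block or within lot 1, differences of tumours from thymocytes therefore rest on tumour 6 alone. A p-value within lot 1 measures no spread between tumours.

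Ikzf1 itself was read first. Its brighter probe set gave 625.9 and 400.6 in wild-type thymocytes, 559.5 and 263.9 in IkL/L thymocytes, and 150.6, 232.3, 387.6, 174.6, 232.5 and 185.4 in tumours 1 to 6. The log2 difference was -1.21 ± 0.39 between tumours and wild-type thymocytes (adjusted p = 0.170), -0.83 ± 0.39 between tumours and IkL/L thymocytes (adjusted p = 0.282) and -0.38 ± 0.48 between the thymocyte genotypes (adjusted p = 0.999). Where this probe set lies relative to the altered part of the gene was not known, and a probe set outside that part checks nothing about the genotype.

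Tumours had strongly raised Notch-pathway transcripts when compared with wild-type thymocytes. Dtx1, a Notch target that encodes a ubiquitin ligase, rose 10.8-fold from 418 ± 253 (n = 2) to 4197 ± 1208 (n = 6; log2 3.43 ± 0.37, adjusted p = 0.00259). Hes1, a transcriptional repressor induced by Notch, rose 4.59-fold from 178.5 ± 22.2 to 824 ± 114 (adjusted p = 0.00161). The receptor gene Notch1 rose 3.23-fold (adjusted p = 0.00945), from 1637 ± 267 to 5331 ± 1093. Myc, a growth regulator downstream of Notch in T cells, rose 2.80-fold (adjusted p = 0.0168), from 232 ± 41.8 to 653 ± 111. Notch3, Ptcra and Il2ra, all expressed in immature thymocytes, did not pass, with log2 differences of 1.10 (adjusted p = 0.177), 1.36 (adjusted p = 0.0698) and 1.495 (adjusted p = 0.368). The list of Notch receptors and T-lineage Notch targets moved by a median log2 of 1.28 (adjusted p = 1.96e-05; adjusted p = 0.203 with an estimated correlation). Among its 14 tested genes 4 rose, 1 fell and 9 did not pass over all probe sets, and 9 rose and 1 fell when adjusted over the list alone. Blocking on chip lot, hybridization day, fluidics module and fluidics run gave list medians of 1.22, 1.22, 1.33 and 1.10. Because all thymocyte arrays shared a lot and a day, the median was the same within lot 1 and within day 1. With lot as a block Dtx1 had a log2 difference of 3.19 (adjusted p = 0.0518), Hes1 of 2.20 (adjusted p = 0.0352), Notch1 of 1.32 (adjusted p = 0.132) and Myc of 1.003 (adjusted p = 0.204). With day as a block the values were 3.19 (adjusted p = 0.0221), 1.99 (adjusted p = 0.0221), 1.48 (adjusted p = 0.058) and 1.36 (adjusted p = 0.127). With module as a block Dtx1, Hes1 and Notch1 passed and Myc did not (1.43, adjusted p = 0.138). With run Dtx1 passed (adjusted p = 0.041), but Hes1 (2.11, adjusted p = 0.101), Notch1 (1.31, adjusted p = 0.251) and Myc (1.54, adjusted p = 0.264) did not.

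**Figure D1:**
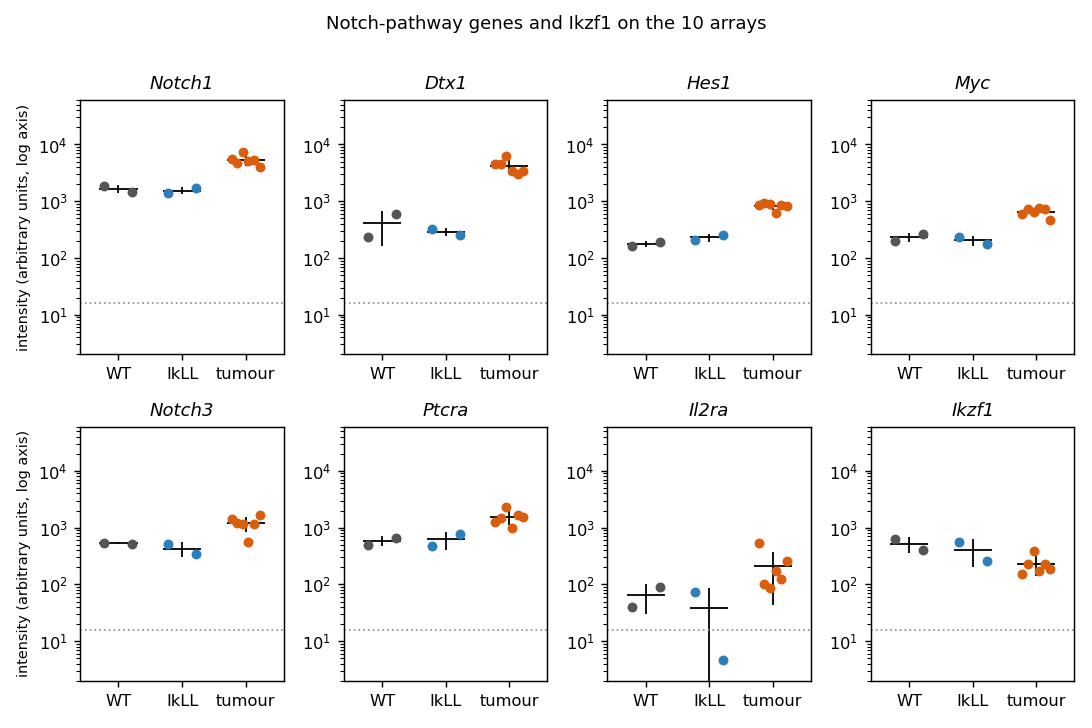
Intensity (arbitrary units, logarithmic axis) of Notch-pathway genes and Ikzf1 on each array, with mean and SD per group. Hes1 spanned 609.5 to 946.1 in tumours against 162.8 and 194.2 in wild-type and 203.8 and 257.5 in IkL/L thymocytes; the dotted line is the floor of 16.

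Genes of later thymocyte stages were lower in the tumours than in wild-type thymocytes. Rag1 and Rag2, which encode the recombinase of antigen-receptor genes, fell 3.67-fold (9218 ± 2548 to 2546 ± 730, adjusted p = 0.0155) and 8.90-fold (908.5 ± 15.6 to 123 ± 75.04, adjusted p = 0.0313). The double-positive thymocyte genes shifted by a median log2 of -1.13 (adjusted p = 6.96e-05; adjusted p = 0.293 with an estimated correlation), with 0 of 14 rising and 2 falling, and 6 falling when adjusted over the list alone. Cd4 and Cd8a, the co-receptor genes, had log2 differences of -2.74 (adjusted p = 0.05001) and -2.11 (adjusted p = 0.086). The mature single-positive genes shifted by -1.17 (adjusted p = 0.000205; adjusted p = 0.213 with an estimated correlation), with 1 of 11 falling and none rising, and 5 falling over the list alone. The member that fell was Ccr7, a chemokine receptor of T cells leaving the thymic cortex (6.94-fold, with 1 tumour at the floor, adjusted p = 0.0266), while Ltb and Cd5 had log2 differences of -2.40 (adjusted p = 0.0535) and -1.36 (adjusted p = 0.0964). The early progenitor and double-negative genes rose as a list by 0.99 (adjusted p = 0.00413; adjusted p = 0.203 with an estimated correlation), although none of its 9 genes passed over all probe sets and 2 rose over the list alone. That call was lost with the stricter filter. Lmo2 had 0.99 (adjusted p = 0.0897) and Spi1 1.14 (adjusted p = 0.237). Under blocks for lot, day, module and run the medians were -0.56 (adjusted p = 0.137), -1.52, -1.15 and -1.54 for double-positive genes, -0.65, -1.44, -1.23 and -1.56 for single-positive genes and 1.27, 0.92, 0.82 and 1.08 for early genes. Within lot 1 the double-positive median was also -0.56, from tumour 6 alone. Rag1, Rag2 and Ccr7 passed with none of the blocks. Rag1 had -1.45 (adjusted p = 0.197), -1.92 (adjusted p = 0.0648), -1.57 (adjusted p = 0.127) and -1.63 (adjusted p = 0.272). Rag2 had -2.46 (adjusted p = 0.29), -3.40 (adjusted p = 0.0817), -3.16 (adjusted p = 0.118) and -3.38 (adjusted p = 0.272).

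Transcripts of other thymic cell types moved in opposite directions. Ccl25, a chemokine made by thymic epithelium, fell 9.57-fold from 379 ± 219 to 39.7 ± 17.2 (adjusted p = 0.0125), and Krt8 fell 10.6-fold from 332 ± 168 to 35 ± 27.4 (adjusted p = 0.0203). Krt18 fell 5.91-fold (adjusted p = 0.00392) and Ctsl, a protease of cortical epithelium, fell 9.50-fold (adjusted p = 0.0227). The thymic epithelial list shifted by a median log2 of -2.56 (adjusted p = 1.96e-05; adjusted p = 0.203 with an estimated correlation), and 4 of its 7 genes fell by either adjustment. Apoe, abundant in macrophages, rose 6.85-fold from 968 ± 278 to 6819 ± 2254 (adjusted p = 0.007). The complement genes C1qb, C1qc and C1qa rose 4.73-fold, 2.72-fold and 2.46-fold (adjusted p = 0.0105, 0.0313 and 0.0371), although C1qb had another probe set of opposite sign. The myeloid list moved by 1.03 (adjusted p = 9.74e-06; adjusted p = 0.264 with an estimated correlation) with 4 of 17 genes rising and 8 rising over the list alone. Stromal and endothelial genes moved by 1.09 (adjusted p = 0.000492; adjusted p = 0.321 with an estimated correlation) with 3 of 15 rising and 6 over the list alone. Fn1 (4.67-fold, adjusted p = 0.0318) and Mgp (7.71-fold, with 1 wild-type array at the floor, adjusted p = 0.0482), which encode matrix proteins, were among the stromal members that rose, and Dcn had a log2 difference of 2.73 (adjusted p = 0.0733). Under blocks for lot, day, module and run the medians were -2.35, -2.62, -2.28 and -3.15 for epithelial, 0.79, 0.70, 1.20 and 0.58 for myeloid and 1.31, 0.63, 1.01 and 1.16 for stromal genes. With the same blocks C1qb had 1.73 (adjusted p = 0.157), 1.95 (adjusted p = 0.0543), 2.33 (adjusted p = 0.112) and 1.60 (adjusted p = 0.231). C1qa had 0.89, 1.05, 1.51 and 0.86 and C1qc 1.02, 1.16, 1.70 and 0.97. Neither these nor Ctsl, Fn1 and Mgp passed with any block. Apoe passed with module only (3.21, adjusted p = 0.0188), and Krt8 with day only, while Krt18 and Ccl25 passed with day and with run. The Mgp call was also lost with a pseudocount. Within run 1 alone the myeloid list was no longer called (adjusted p = 0.061). With tumour 6 left out and day as a block neither the myeloid, the stromal, the early nor the cholesterol list was called, and the Notch list had a median of 1.12 (adjusted p = 0.0702).

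**Figure D2:**
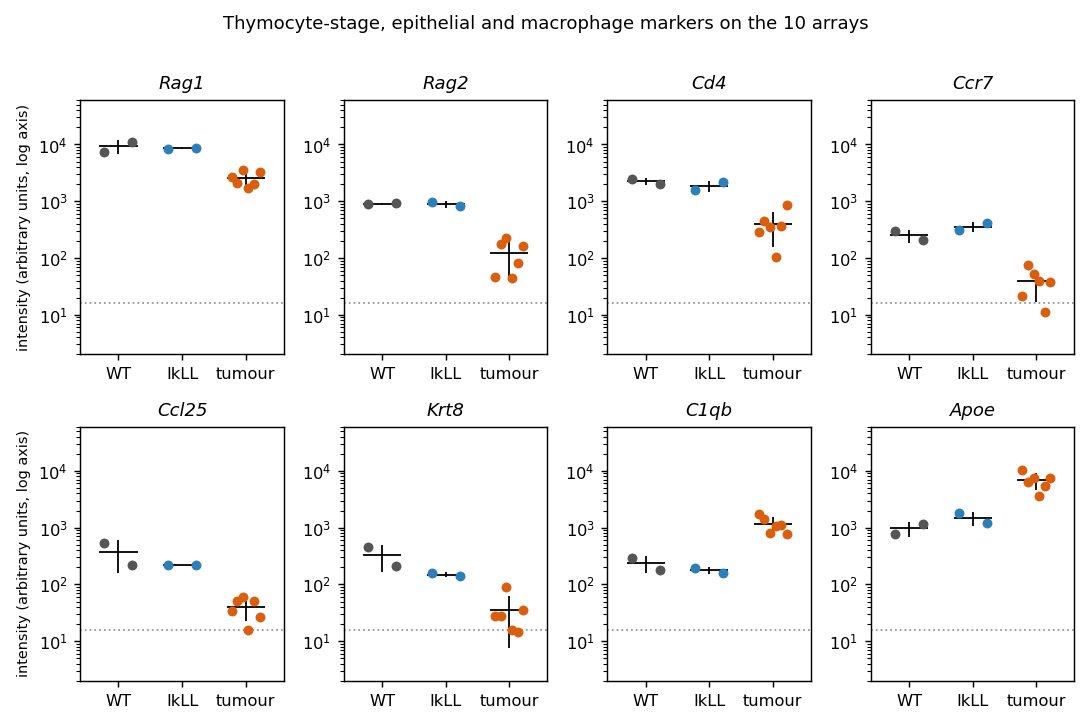
Intensity (arbitrary units, logarithmic axis) of thymocyte-stage genes (Rag1, Rag2, Cd4, Ccr7), epithelial genes (Ccl25, Krt8) and macrophage genes (C1qb, Apoe) on each array, with mean and SD per group. Rag1 averaged 2546 in tumours, 9218 in wild-type and 8504.5 in IkL/L thymocytes.

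Growth and metabolic lists shifted by small amounts per gene. The list of Myc-regulated growth and ribosome biogenesis rose by 0.78 (adjusted p = 8.98e-08; adjusted p = 0.264 with an estimated correlation). All 23 genes had positive differences and none passed by either adjustment. Rrs1, Nop58 and Polr1b had log2 values of 1.04, 0.85 and 0.91. Glycolysis and glucose uptake rose by 0.64 (adjusted p = 0.0259; adjusted p = 0.494 with an estimated correlation), with 10 of 14 genes positive and none passing; Pgam1 and Aldoa had 1.05 and 0.93. The glycolysis call was lost without tumour 3 (adjusted p = 0.0525), tumour 4 (adjusted p = 0.0509) or the second wild-type array (adjusted p = 0.0964), and the median was -0.0392 (adjusted p = 0.57) with lot as a block. With day, module and run as blocks it was 0.53 (adjusted p = 0.0673), 0.70 and 0.40 (adjusted p = 0.2). Cholesterol synthesis fell by 0.42 (adjusted p = 0.00651; adjusted p = 0.293 with an estimated correlation) with all 12 genes negative and none passing, among them Fdps (-1.06) and Idi1 (-0.91). Its block medians were -0.70, -0.48, -0.18 (adjusted p = 0.157) and -0.43 (adjusted p = 0.0975). Apoptosis regulators fell by 0.18 (adjusted p = 0.0155; adjusted p = 0.293 with an estimated correlation), with 2 of 15 falling and 1 rising and 3 falling over the list alone. Those 2 were the death receptor Fas (7.56-fold, with 3 tumours at the floor, adjusted p = 0.0205) and the survival gene Bcl2l1 (3.01-fold, adjusted p = 0.0295). With the 4 blocks Fas had -1.65 (adjusted p = 0.257), -1.98 (adjusted p = 0.0677), -3.53 (adjusted p = 0.0735) and -2.41 (adjusted p = 0.113). Bcl2l1 had -0.83 (adjusted p = 0.303), -1.42 (adjusted p = 0.159), -1.63 (adjusted p = 0.133) and -1.43 (adjusted p = 0.401). Both calls were lost with each block. The apoptosis call was lost without the second wild-type array (adjusted p = 0.0691), and its block medians were -0.18 (adjusted p = 0.17), -0.26, -0.30 (adjusted p = 0.086) and -0.18. With the stricter filter neither the cholesterol nor the apoptosis list was called. Block medians of the Myc list were 0.38, 0.73, 0.66 and 0.79.

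The remaining lists were not called against wild-type thymocytes in the fit without blocks, although several were called in other settings. The Ikaros family and T-lineage transcription factors had a median of -0.37 (adjusted p = 0.0576). Egr2, a transcription factor induced by T-cell receptor signals, fell 5.24-fold (adjusted p = 0.0103), and Id2, an inhibitor of E proteins, rose 2.54-fold (adjusted p = 0.0442). Of the 14 genes 12 did not pass, and 2 rose and 5 fell over the list alone. T-cell receptor genes had -0.20 (adjusted p = 0.0631), oxidative phosphorylation 0.23 (adjusted p = 0.0631), MHC class II and dendritic-cell genes -0.72 (adjusted p = 0.0544), cell cycle genes -0.14 (adjusted p = 0.111) and adipose genes 1.08 (adjusted p = 0.106), with no member passing. Of 11 leukaemia oncogenes and tumour suppressors (median 0.05, mean -0.12, test downward, adjusted p = 0.542) 1 rose and 2 fell, namely Myc upwards, Pim1 (adjusted p = 0.0242) and Ccnd3 (3.86-fold, adjusted p = 0.024) downwards. Pim1 and Ccnd3 passed with no block, Egr2 with module only and Id2 with lot only. Interferon and MHC class I genes (-0.09, adjusted p = 0.706), protein folding (0.05, adjusted p = 0.542), B-cell (-0.34, adjusted p = 0.316) and gamma-delta genes (0.20, adjusted p = 0.968) had no passing member among probe sets with 1 symbol. Cytotoxic (0.17, adjusted p = 0.579) and erythroid genes (0.08, adjusted p = 0.706) had none either, and their means were of the opposite sign (-0.02 and -0.08). With run as a block 5 of these lists were called, namely transcription factors (-0.54, adjusted p = 0.0317), T-cell receptor (-0.68, adjusted p = 0.0276), oxidative phosphorylation (0.36, adjusted p = 0.0276), MHC class II (-0.47, adjusted p = 0.0471) and interferon genes (-0.46, adjusted p = 0.0276). With day as a block transcription factors (-0.42, adjusted p = 0.0362), oxidative phosphorylation (0.35, adjusted p = 0.0039) and adipose genes (1.10, adjusted p = 0.0383) were called. Cell cycle genes were called with lot (-0.32, adjusted p = 0.00889) and module (-0.37, adjusted p = 0.000328). Of the alternatives 9 called transcription factors, 9 MHC class II, 8 oxidative phosphorylation, 5 cell cycle, 4 T-cell receptor, 3 adipose, 2 interferon and 1 B-cell genes.

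Over all 7172 tested probe sets 135 passed between tumours and wild-type thymocytes, 72 higher and 63 lower, from 59 and 56 genes and 14 probe sets without a unique symbol. The median fold among them was 4.08 and the smallest 1.92. Among the largest rises were Ccl8 (68.7-fold, 17 ± 2.12 to 1349 ± 720.0), a monocyte-attracting chemokine, Saa3 (49.2-fold), an acute-phase protein, Fbp1 (28.1-fold), a gluconeogenic enzyme, Ccl9 (10.7-fold) and Cxcl13 (at least 16.7-fold). The floor of 16 enters these folds, since 1 of the 2 wild-type arrays, and for Cxcl13 both, lay at it, so they have no order among them. Rises measured on both sides were Trgv1 (12.9-fold), Pdgfrb (12.7-fold), Pbx3 (11.6-fold), Dtx1 and Bmp7 (10.5-fold). Among the largest falls were Akr1c13 (11.2-fold), Wdr78 (10.4-fold), Ctsl, Rag2 and S100a10 (7.64-fold), together with Tdrp (16.7-fold), Krt8, Napsa (10.6-fold), Ccl25 and Traf1 (at least 7.84-fold), which lay at the floor in 2, 2, 4, 1 and 6 tumours. S100a10 had another probe set of opposite sign. Probe set 92328_at, for which no gene name was available, fell 39.9-fold from 1347 ± 158 to 43.3 ± 41.9. Unadjusted p under 0.05 was reached by 1136 probe sets where 358.6 would be reached by chance, and 17.9% of probe sets had no overlap between groups against 7.14% by chance. With lot, day, module and run as blocks 33, 52, 49 and 9 probe sets passed, of which 15, 37, 34 and 8 were among the 135. Within lot 1, day 1 and run 1, 22, 26 and 0 probe sets passed (362 unadjusted in the last). Of the 38 named genes that had passed, 6, 14, 14 and 6 passed with these blocks. The count was 75 without tumour 5, 221 without tumour 6, 14 without the first and 29 without the second wild-type array. In each setting every one of the 135 that was tested kept its direction, and 92 of them were tested with the stricter filter and 108 with 1 probe set per gene. As none of the 135 had overlap between the arrays of the groups, most settings could not have reversed their direction.

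Tumours also differed from thymocytes of their own genotype, chiefly in the same genes. Dtx1 rose 14.0-fold from 291 ± 47.7 (n = 2; log2 3.81 ± 0.37, adjusted p = 0.00388). Hes1 rose 3.57-fold from 231 ± 38.0 (adjusted p = 0.00566), and Notch1 3.42-fold from 1543 ± 217 (adjusted p = 0.00822). Myc rose 3.19-fold from 204 ± 41.9 (adjusted p = 0.012). Notch3, Ptcra and Il2ra had log2 differences of 1.44 (adjusted p = 0.082), 1.31 (adjusted p = 0.0746) and 2.32 (adjusted p = 0.137). Rag1 fell 3.46-fold from 8504.5 ± 159.5 (adjusted p = 0.0211) and Rag2 8.71-fold from 893 ± 120 (adjusted p = 0.0374). The Notch list rose by a median log2 of 1.37 (adjusted p = 3.13e-06; adjusted p = 0.190 with an estimated correlation), with 4 of 14 genes rising, and 8 rising and 1 falling over the list alone. Double-positive genes fell by 1.43 (adjusted p = 0.000397; adjusted p = 0.290 with an estimated correlation), 2 of 14 falling and 6 over the list alone. Single-positive genes fell by 1.07 (adjusted p = 0.000798; adjusted p = 0.290 with an estimated correlation), 1 of 11 falling (Ccr7, 10.004-fold, with 1 tumour at the floor, adjusted p = 0.0151) and 4 over the list alone. Early genes had 0.38 (adjusted p = 0.0613) with no gene passing and 2 rising over the list alone. With lot, day, module and run as blocks they had 0.78 (adjusted p = 0.0377), 0.43 (adjusted p = 0.0766), 0.46 (adjusted p = 0.0195) and 0.57 (adjusted p = 0.0223). They were also called within day 1 (adjusted p = 0.0448). Within lot 1 their median was that of the lot block, from tumour 6 alone. Block medians for lot, day, module and run were 1.27, 1.12, 1.52 and 1.18 for Notch, -0.56 (adjusted p = 0.132), -1.31, -1.06 and -1.15 for double-positive and -0.90, -1.41, -0.94 and -1.26 for single-positive genes. For double-positive genes too, the median within lot 1 was that of the lot block, from tumour 6 alone. With lot as a block Dtx1, Hes1, Notch1 and Myc had 3.58 (adjusted p = 0.0543), 1.83 (adjusted p = 0.0626), 1.40 (adjusted p = 0.147) and 1.19 (adjusted p = 0.181). With day as a block they had 3.57 (adjusted p = 0.022), 1.62 (adjusted p = 0.0493), 1.56 (adjusted p = 0.0516) and 1.55 (adjusted p = 0.097). Rag1, Rag2 and Ccr7 passed with none of the blocks. With lot Rag1 had -1.36 (adjusted p = 0.259) and Rag2 -2.43 (adjusted p = 0.348).

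Epithelial, myeloid, stromal, growth and metabolic lists differed from IkL/L thymocytes as well. Thymic epithelial genes fell by 1.72 (adjusted p = 0.000175; adjusted p = 0.290 with an estimated correlation), with Ccl25 (6.04-fold, with 1 tumour at the floor, adjusted p = 0.0374) and Krt18 (3.29-fold, adjusted p = 0.0249) falling out of 7 and 4 over the list alone. Myeloid genes rose by 0.73 (adjusted p = 0.000175; adjusted p = 0.290 with an estimated correlation), 5 of 17 rising and 8 over the list alone, among them C1qb (6.25-fold, adjusted p = 0.00708), C1qa (3.80-fold, adjusted p = 0.00822) and Apoe (4.42-fold, adjusted p = 0.0211). Here too C1qb had another probe set of opposite sign. Stromal genes rose by 0.87 (adjusted p = 0.0142; adjusted p = 0.414 with an estimated correlation), 1 of 15 rising and 4 over the list alone. MHC class II and dendritic-cell genes fell by 0.99 (adjusted p = 0.0304; adjusted p = 0.290 with an estimated correlation) with none of 13 passing. Myc-regulated growth rose by 0.79 (adjusted p = 1.05e-08; adjusted p = 0.290 with an estimated correlation) with none of 23 genes passing and 13 rising over the list alone. Glycolysis rose by 0.87 (adjusted p = 9.99e-05; adjusted p = 0.290 with an estimated correlation) with none of 14 passing and 7 rising over the list alone. Oxidative phosphorylation rose by 0.37 (adjusted p = 0.00167; adjusted p = 0.367 with an estimated correlation) with none of 21 passing. Rrs1, Pgam1 and Sdhd had log2 differences of 1.38, 1.53 and 0.88. Apoptosis regulators fell by 0.41 (adjusted p = 0.00466; adjusted p = 0.290 with an estimated correlation), Fas (7.16-fold, with 3 tumours at the floor, adjusted p = 0.0245) and Bcl2l1 (3.37-fold, adjusted p = 0.0211) falling among 15 and 5 over the list alone. Ikaros-family and T-lineage transcription factors fell by 0.33 (adjusted p = 0.0427; adjusted p = 0.414 with an estimated correlation), 1 of 14 falling (Egr2, 6.08-fold, adjusted p = 0.00822) and 5 over the list alone. Block medians for lot, day, module and run were -2.06, -1.91, -1.82 and -2.85 for epithelial, 0.64, 0.42, 0.74 and -0.03 (adjusted p = 0.196) for myeloid, 1.60, 0.95, 1.39 and 0.67 for stromal and -0.84, -0.74, -0.92 and -0.83 for MHC class II genes. They were 0.50, 0.86, 0.81 and 0.99 for Myc-regulated growth, 0.26 (adjusted p = 0.244), 0.92, 0.69 and 0.70 for glycolysis and 0.28, 0.48, 0.36 and 0.35 for oxidative phosphorylation. For apoptosis they were -0.26, -0.45, -0.38 and -0.32, and -0.27 (adjusted p = 0.287), -0.51, -0.19 (adjusted p = 0.0629) and -0.77 for transcription factors.

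Several of these calls depended on individual arrays or on the setting. The transcription-factor list was lost without tumour 1 (adjusted p = 0.0747), tumour 4 (adjusted p = 0.0636), tumour 6 (adjusted p = 0.0538) or the first IkL/L array (adjusted p = 0.123). The MHC class II list was lost without tumour 6 (adjusted p = 0.0538) or the second IkL/L array (adjusted p = 0.0543), and the stromal list without tumour 6 (adjusted p = 0.0657) or the first IkL/L array (adjusted p = 0.151). With day as a block and tumour 6 left out neither the MHC class II, the myeloid nor the stromal list was called. Without a filter the MHC class II and stromal lists were lost, with array weights the MHC class II and transcription-factor lists, and with the stricter filter the stromal list. The lists not called without blocks were T-cell receptor genes (-0.36, adjusted p = 0.124), cholesterol synthesis (-0.25, adjusted p = 0.197), leukaemia genes (-0.15, adjusted p = 0.678, 1 of 11 rising), B-cell genes (-0.58, adjusted p = 0.167), gamma-delta genes (-0.10, adjusted p = 0.886), erythroid genes (0.27, adjusted p = 0.886) and adipose genes (1.18, adjusted p = 0.0613), of which Lpl, a lipoprotein lipase, rose 6.08-fold (adjusted p = 0.0409). Cell cycle (median -0.11, mean 0.02, adjusted p = 0.983), interferon (0.02, mean -0.03, adjusted p = 0.886), protein folding (0.00, mean -0.08, adjusted p = 0.983) and cytotoxic genes (-0.63, test upward, adjusted p = 0.892) differed in sign between measures. With blocks some of them were called. Adipose genes were called with lot (0.79, adjusted p = 0.0419), day (1.20, adjusted p = 0.0149) and module (1.45, adjusted p = 0.0195), and in 11 of 27 alternatives. Cholesterol synthesis was called with lot (-0.47, adjusted p = 0.0218) and module (-0.40, adjusted p = 0.0269). With run T-cell receptor (-0.98, adjusted p = 0.0242), B-cell (-1.38, adjusted p = 0.019) and interferon genes (-0.75, adjusted p = 0.0242) were called, although no run held both tumours and IkL/L arrays. Of all tested probe sets 102 passed, 65 higher and 37 lower, from 54 and 31 genes and 13 probe sets without a unique symbol, with a median fold of 4.43 and a smallest of 1.95. Among the largest rises were Dtx1, Mt1 (8.68-fold), Ccl9 (7.66-fold) and Serping1 (7.41-fold), together with Fbp1 (at least 56.1-fold), Ccl8 (32.1-fold), Cxcl13 (at least 16.7-fold), Pdgfrb (10.7-fold), Pbx3 (10.4-fold) and Cd5l (at least 9.17-fold), for which 2, 1, 2, 1, 1 and 2 IkL/L arrays lay at the floor. Among the largest falls were Tdrp (15.3-fold, with 2 tumours at the floor), Ccdc186 (12.1-fold, with 3), Ccr7, Wdr78 (9.31-fold), Rag2, Fas, S100a10 (6.49-fold), Egr2, Ccl25 and Traf1 (at least 5.31-fold). Unadjusted p under 0.05 was reached by 1369 probe sets, and 22.5% had no overlap between groups against 7.14% by chance. With lot, day, module and run as blocks 17, 42, 21 and 0 probe sets passed (433 unadjusted in the last), of which 4, 27, 16 and 0 were among the 102. Within lot 1 and day 1, 8 and 20 passed. Of the 31 named genes that had passed, 1, 11, 6 and 0 passed with these blocks. Fas, Bcl2l1, C1qa, Apoe, Krt18 and Lpl passed with none. Leaving out tumour 6 gave 332, the first IkL/L array 7 and the second 23.

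**Figure D3:**
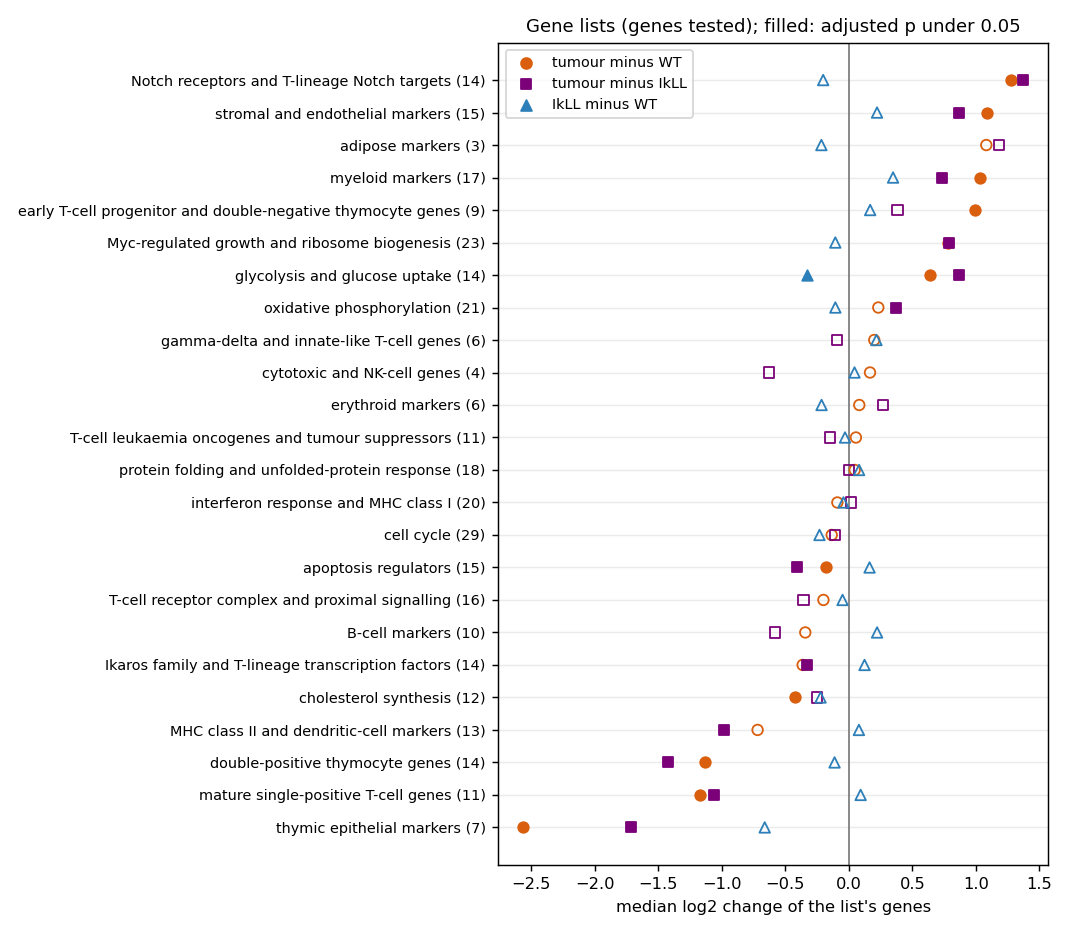
Median log2 change of each gene list (horizontal axis) in the 3 comparisons, filled where the adjusted p was under 0.05. The Notch list lay at 1.28 and 1.37 for tumours against wild-type and IkL/L thymocytes and at -0.20 between the thymocyte genotypes.

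Few differences between the genotypes were detected in unfractionated thymocytes of 3-week-old mice. Power was low, as 16.4% of simulated 2-fold changes were called in this comparison. Notch1 (log2 -0.08), Hes1 (0.37), Dtx1 (-0.38), Myc (-0.19), Notch3 (-0.34), Ptcra (0.05) and Il2ra (-0.82) all had an adjusted p of 0.999, and the Notch list had a median of -0.20 (adjusted p = 0.501). An unadjusted p under 0.05 was reached by 230 probe sets where 358.6 would be by chance, but by 419 with only the 2 thymocyte groups in the limma fit. The first count thus depends on the spread shared with the tumours. In the fit with all groups 1 of 7172 probe sets passed. That probe set, 160799_at, for which no gene name was available, fell at least 10.4-fold (log2 -3.38 ± 0.26, adjusted p = 0.000725), from 177.6 and 155.3 in wild-type to 15.2 and 7.6 in IkL/L thymocytes. In tumours it gave 3.8 to 23.3. The genes with the smallest unadjusted p were given as values only: Cask (at least 4.50-fold higher, adjusted p = 0.268), a membrane scaffold kinase, Gpn3 (log2 1.46), H2bc22 (2.46), G6pc (1.35) and Cd96 (3.55 ± 0.83, adjusted p = 0.938) on the positive side. On the negative side they were Napsa, an aspartic protease (-2.43 ± 0.36, adjusted p = 0.175), Fxyd2 (-2.44), Eya3 (-1.85), Pstk (-1.38) and Rnh1 (-2.51). No overlap between groups was seen for 39.4% of probe sets against 33.3% by chance. With lot, day, module and run as blocks 2, 1, 0 and 0 probe sets passed, none passed within lot 1 (419 unadjusted), day 1 (192) or run 2 (396), and 2 passed without tumour 6 or without either wild-type array.

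Of the 24 lists only glycolysis and glucose uptake was called between the thymocyte genotypes, lower by 0.33 in IkL/L (adjusted p = 0.0268; adjusted p = 0.849 with an estimated correlation). None of its 14 genes passed, 12 were negative, and Pgk1 (-0.69), Slc2a1 (-2.12) and Pkm (-0.68) had the smallest p values. The call was lost with the stricter filter, where stromal genes (0.66, adjusted p = 0.00972) were called instead. It was also lost without the first (adjusted p = 0.171) or second wild-type array (adjusted p = 0.0833) and without the second IkL/L array (adjusted p = 0.575), and without the first IkL/L array it was -0.61 (adjusted p = 0.000836). With lot, day, module and run as blocks the median was -0.33 (adjusted p = 0.0145), -0.33 (adjusted p = 0.0245), -0.06 (adjusted p = 0.634) and -0.25 (adjusted p = 0.196), and within run 2 it was -0.25 (adjusted p = 0.0677). With module as a block the cell cycle list (-0.55) and oxidative phosphorylation (-0.28) were called instead. The T-cell lists had medians of 0.17 (early), -0.11 (double-positive), 0.09 (single-positive), -0.05 (T-cell receptor), 0.12 (transcription factors), 0.22 (gamma-delta) and 0.04 (cytotoxic). The growth lists had -0.11 (Myc), -0.23 (cell cycle), -0.11 (oxidative phosphorylation), -0.22 (cholesterol), 0.16 (apoptosis), 0.08 (protein folding), -0.04 (interferon) and -0.03 (leukaemia genes, mean 0.02). Other cell types had 0.22 (B-cell), 0.08 (MHC class II), 0.35 (myeloid), -0.22 (erythroid), 0.22 (stromal), -0.66 (thymic epithelial) and -0.22 (adipose).

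Changes of the tumours were compared with the difference between the thymocyte genotypes. Of the probe sets called between tumours and wild-type thymocytes, 105 of 135 (77.8%) had the same sign between IkL/L and wild-type thymocytes, and among those called against IkL/L thymocytes 40 of 102 (39.2%) did. In the first share the wild-type arrays enter both differences, which raises agreement. In the second the IkL/L arrays enter with opposite signs, which lowers it. Neither share was set beside a simulated one, so neither was read as a shared effect. For the differences from wild-type thymocytes, arrays simulated without any genotype effect were used as a yardstick. The observed correlation was 0.269 and the simulated mean 0.561, and the covariance was 0.0857 against 0.0954. The simulated tumours carried no changes. Tumour changes unrelated to the genotype lower the observed correlation but not the covariance, so only the covariances are alike in this respect. When each difference used a different wild-type array, the correlation was 0.0152 and -0.0902. Only 160799_at passed in both comparisons, in the same direction. The tumour comparisons, which share the 6 tumour arrays, had 70 calls in common, all in the same direction; the correlation of their log2 differences was 0.783 against 0.371 simulated without effects, and the covariance 0.386 against 0.0562. Independent draws would share 0.00878 and 0.978 calls, values that leave out the shared arrays, so no excess over them was read as a shared effect.

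Tumours varied more between each other than thymocyte preparations did. As the tumours lay on lots 1 and 2 and days 1 to 3 and all thymocyte arrays on lot 1 and day 1, batch may enter this difference. The median SD of log2 intensity was 0.393 among tumours, 0.213 among wild-type and 0.185 among IkL/L thymocytes, and 0.349 among tumours without tumour 6. A median SD from 2 arrays runs lower than one from 6, and the root mean square SDs were closer, at 0.582, 0.455 and 0.417. Correlations ran from 0.894 to 0.918 among tumours 1 to 5 and from 0.856 to 0.877 between tumour 6 and the others, against 0.934 and 0.940 within the thymocyte groups. Tumour 6 also had the highest ratios of 3' to 5' signal, 2.94 for Actb (other arrays 1.53 to 2.33) and 1.21 for Gapdh (0.92 to 1.06), and the fewest values below the floor (15.4%). The leading principal components held 34.4% and 14.6% of the variance. Genes on chromosome 15 of GRCm38.p6 had a median log2 shift of 0.30 (1.23-fold, 149 of 228 genes above the tumour's own median) in tumour 2 and 0.31 (1.24-fold, 147 of 228) in tumour 5, against -0.09 to 0.02 in the other tumours. Genes on chromosome 12 had 0.29 (1.22-fold, 121 of 180 genes) in tumour 2 and 0.27 (1.20-fold, 120 of 180) in tumour 3, against 0.03 to 0.11 in the other tumours. Each of these 4 pairs had a permutation p of 0.0001, the smallest that the random gene lists can give, and an adjusted p of 0.0024 over the pairs of tumour and chromosome. Of the 120 pairs in tumours 6 passed. The other 2, both in tumour 6, were a rise of chromosome 1 (0.16, also with an adjusted p of 0.0024) and a fall of chromosome 7 (-0.0955, adjusted p = 0.049995). Of the 80 pairs in thymocytes none passed (-0.11 to 0.07).

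**Figure D4:**
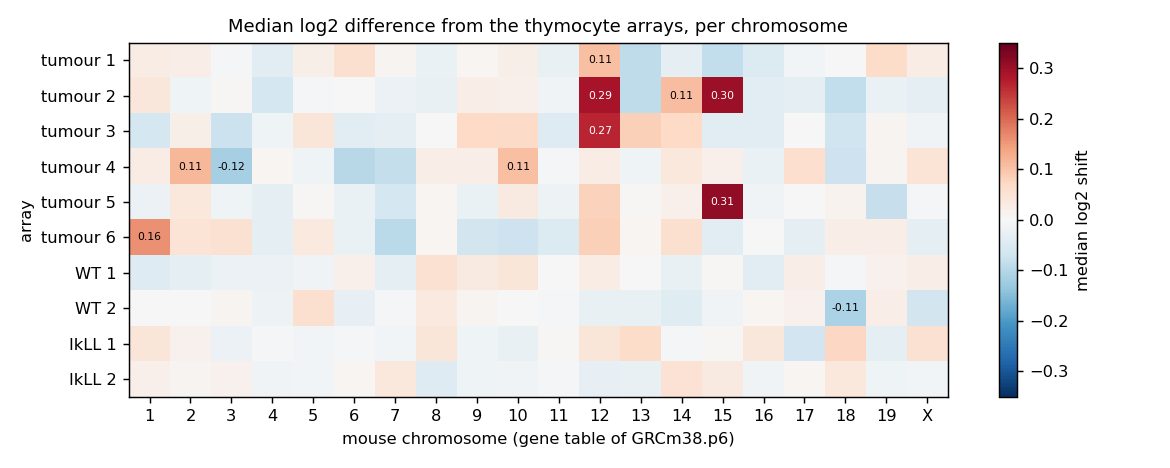
Median log2 difference from the thymocyte arrays for the genes of each chromosome (horizontal axis) on each array (vertical axis). Chromosome 15 reached 0.30 and 0.31 in tumours 2 and 5 and chromosome 12 reached 0.29 and 0.27 in tumours 2 and 3.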

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

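Among 186 genes read on the 6 tumour arrays, Dixon's test at its 5% point set a tumour apart in 12, where 9.3 would be by chance, since about 1 in 20 genes is set apart without cause. In tumour 1 Sh2d1a, an adaptor of T-cell signalling, was low (195.5, others 395.6 to 580.5), and in tumour 2 Pax5, a B-cell factor, was low (23.8, others 89.3 to 131.3). Tumour 3 had high Ccdc186 (113.2, others 8.4 to 23.1) and low Saa3 (71.8, others 782.6 to 3239.6), with 10.6 to 27.8 in the thymocytes, so Saa3 was higher than in thymocytes in tumour 3 too, but by less. In tumour 4 the transferrin receptor Tfrc (3304.6, others 1311 to 1651.5) and the mitotic kinase Plk1 (2055.1, others 1060.2 to 1189.8) were high, while Hes1 (609.5, others 815.6 to 946.1) and Notch3 (562.6, others 1168.5 to 1680.7) were low. Tumour 5 had low Igll1 (22.9, others 86.9 to 125.8). In tumour 6 Id2 was high (1340.6, others 735.9 to 879) and Fdps (308.3, others 807.9 to 1032.1) and Rnh1 (41.8, others 148.5 to 233.9) were low.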

How the results depend on the processing

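No named gene that had passed changed sign in any setting (1054 values against wild-type and 827 against IkL/L thymocytes). All 135 and 102 called probe sets had no overlap between the arrays of the groups compared. With an array left out, another filter, floor or weights, or lot or day separated, their sign could not have reversed. The kept signs are therefore little evidence of stability. Counts moved with the setting, and the cause was not tested. Tumours against wild-type thymocytes gave 135 probe sets, 14 to 221 with an array left out, 77 without a filter, 322 with array weights, 33, 52, 49 and 9 with lot, day, module and run as blocks, 22, 26 and 0 within lot 1, day 1 and run 1, and 250 with day as a block without tumour 6. Their 11 called lists became 11 to 13 with an array left out, 7 with the stricter filter (where the apoptosis, cholesterol and early lists were lost and the epithelial list was not tested), 8 with day as a block without tumour 6, 14 with the run block and within day 1, 15 with trend and robust eBayes and 0 with the estimated correlation. Tumours against IkL/L thymocytes gave 102 probe sets, 7 to 332 with an array left out, 163 with quantile normalization, 176 with the floor at the 40th percentile, 166 with the stricter filter, 207 with a trend and robust eBayes, 739 with array weights, 17, 42, 21 and 0 with the 4 blocks, 8 and 20 within lot 1 and day 1, and 376 with day as a block without tumour 6. Their 12 lists became 9 to 14 with an array left out, 15 with the run block and within day 1, and 0 with the estimated correlation. The share of higher probe sets, 53.3% and 63.7%, was 38.0% and 43.8% with the higher floor; it was lowest within day 1 (19.2%) and with the lot block (17.6%) and highest without the second wild-type (69.0%) and the second IkL/L array (82.6%).

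Between the thymocyte genotypes 1 probe set passed, 1 to 2 with an array left out, 15 without a filter, 2 with the lot block, and 0 with the higher floor, the stricter filter, the 2 groups alone, trend and robust eBayes, 1 probe set per gene, the module block, the run block, lot 1 only, day 1 only and run 2 only. The 1 called list, glycolysis, became 0 to 4 with an array left out, 0 with quantile normalization, without a filter, with the run block, within run 2 and with the estimated correlation, and 2 with the 2 groups alone, the module block and lot 1 only; with the stricter filter the count stayed 1, but stromal genes were called and glycolysis was lost. The overlap of 1 probe set was 1 to 2 with an array left out, 7 without a filter, 2 with the lot block, and 0 with the higher floor, the stricter filter, the 2 groups alone, trend and robust eBayes, 1 probe set per gene, the module and run blocks, lot 1 only and day 1 only; the covariance ran from -0.00289 (run block) to 0.245 (module block). The spread between tumours, 0.393, was 0.349 to 0.408 with an array left out.

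Among lists called in the main or the alternative setting, the median reversed its sign in 5 cases. Lists called in neither changed sign more often, such as leukaemia genes in 14 settings against wild-type thymocytes. Glycolysis in tumours against wild-type thymocytes was -0.0392 with the lot block (adjusted p = 0.57) and within lot 1, against 0.64. In tumours against IkL/L thymocytes the cell cycle list was 0.39 with day as a block without tumour 6 (adjusted p = 0.00709), against -0.11. With the run block the interferon list was -0.75 (adjusted p = 0.0242), against 0.02, and the myeloid list -0.0306 (adjusted p = 0.196), against 0.73.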

Other observations

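Some antigen-receptor probe sets differed widely between tumours and others did not. A Trbv1 probe set for a variable segment of the T-cell receptor beta chain gave 13096 in tumour 3 and 10390 in tumour 5, at most 14 in the other tumours, and 1072 to 1691 in the thymocytes, whereas another Trbv1 probe set gave 16997 to 26706 in all tumours and 25726 to 32578 in thymocytes. A Trbv13-2 probe set gave 11067 in tumour 5 and 47.9 to 1152 in the other tumours, against 1571 to 2242 in the thymocytes, but a second Trbv13-2 probe set gave 113.9 in tumour 5 and was highest in tumour 1 (3050.7). Trgv1, a gamma-chain segment, gave 1434 to 15868 in tumours against 329 to 565 in thymocytes and rose 12.9-fold against wild-type (adjusted p = 0.0372) but did not pass against IkL/L thymocytes (adjusted p = 0.0511) or, against wild-type, with lot, day or run as a block (adjusted p = 0.327, 0.09005 and 0.182). A probe set shared by the gamma segments Trgv4 and Trgv2 passed in both comparisons. It rose 5.12-fold against wild-type (adjusted p = 0.00731) and 7.01-fold against IkL/L thymocytes (adjusted p = 0.00483). A Trgv4 probe set gave 1159 to 9543 in tumours and 528 to 956.5 in thymocytes but passed in neither (adjusted p = 0.162 and 0.0966). A Trav9d-3 probe set of the alpha chain fell from at least 11869 in thymocytes to 3255 to 5646 in tumours (log2 -1.46 against wild-type, adjusted p = 0.024). A second Trav9d-3 probe set fell as well (-1.95, adjusted p = 0.0313). Another gave only 93.4 to 137.4 in thymocytes and 18.5 to 71.8 in tumours and did not pass (-1.42, adjusted p = 0.188). Whether the high values of a segment in some tumours came from clonal receptor rearrangement was not tested by these arrays.

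Batch could explain part of the tumour changes, since 5 of 6 tumours lay on a lot without thymocytes; both tests here were chosen after the result was seen, and the lot test, first read as arguing against lot, was set to undecided afterwards because only 1 tumour shares the lot. For lot, the 221 probe sets called without tumour 6 were read in tumour 6 against the IkL/L arrays of its own lot: a median of 58.6% of the change was kept and 200 (90.5%) lay on the same side, whereas tumours 1 to 5 left out in turn kept 70.9% to 91.4%. For day, over 179 probe sets called with the tumours of days 2 and 3, tumour 4 kept 97.5% and tumour 6 64.2%, with 92.7% and 90.5% on the same side, which argues against day as the whole cause. It stays open whether the smaller share kept by tumour 6 was due to its lot, its RNA or the tumour, since it had the highest ratios of 3' to 5' signal (Actb 2.94, other arrays 1.53 to 2.33) and a correlation of at most 0.877 with the other tumours. With lot as a block some differences from IkL/L thymocytes stayed about as large (Dtx1 3.58 from 3.81, Tdrp -4.26 from -3.94) and others shrank (Fas -1.57 from -2.84).

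Myeloid and stromal markers rose and thymic epithelial markers fell in tumours against wild-type thymocytes; the test of macrophage genes was written before its result was seen, the others after, and the criterion for neutrophils was changed after its result to allow for the error of single genes and later for that of the set, with the outcome undecided by either. A lower share of T cells with the mix of other cells unchanged would raise epithelial markers too, so it would not by itself give their median of -2.56. That fall is part of the pattern to be explained, so its value is no independent test. Of 20 macrophage genes outside the lists 9 were tested, all positive with a median of 1.69, and 3 passed (Lgmn 2.02, Slc11a1 2.06 and Pltp 1.69). Marco, Cd5l, Lgmn and Slc11a1 averaged 10.1, 37.65, 61.65 and 40.2 in wild-type thymocytes and less in IkL/L, below every array's median. They were tested only because tumours were high, so their sign was largely fixed by the filter. This holds for Mrc1 of the myeloid list too. Mpeg1 (1.27), Hmox1 (0.92) and Pltp, with wild-type means of at least 199.3, were also higher in tumours. Aif1 (0.03) and Fcgr1 (0.07) hardly moved. More macrophages would give such rises, although higher expression per cell would give the same values. None of 6 neutrophil genes was positive (median -0.58, and -1.04 against IkL/L thymocytes) or passed, whereas all 10 macrophage genes of the myeloid list were positive; as the mean of the neutrophil genes ran from 5.15 to 8.82 between tumours (difference from wild-type -0.52, 95% interval -3.06 to 2.02), more myeloid cells of every kind could be neither held nor ruled out. Whether the tumour cells themselves express Apoe or C1qb, or whether the thymocyte preparations lost macrophages and stroma when cells were released from the tissue, stays open; with the run block the myeloid list, which includes neutrophil genes, was at -0.0306 against IkL/L thymocytes while Apoe, C1qb, C1qa and C1qc had 2.44, 1.65, 1.29 and 0.94, none passing.

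Chromosome 15 genes lay higher in tumours 2 and 5 and chromosome 12 genes in tumours 2 and 3. An extra copy of the whole chromosome may be reflected, in a share of the cells that these values do not give. Tests of scaling and of the extra copy were written before their results were seen, and the tests of chance and of parts of a chromosome after. The test of neighbouring genes was first written over both chromosomes together and then came out in favour of a change in part of a chromosome, and it was afterwards split by chromosome and given an interval, which still favoured a part of chromosome 12 until it was widened for the number of stretches. Scaling is argued against, as at least 88.0% of the shift was kept with quantile normalization. The permutation test of chance gave an adjusted p of 0.0024 in each of the 4 pairs. Its random gene lists treat genes as independent, so genes that vary together could also give such a value. Chromosome 1 in tumour 6 had the same adjusted p with a shift of 0.16. At least 64.5% of the genes lay above the tumour's median, at 1.20-fold to 1.24-fold. The fold that an extra copy gives on these arrays was not measured. On chromosome 15 the dimmer genes moved by 0.102 in tumour 2 and 0.101 in tumour 5, barely above the lower limit set for an extra copy. Its brighter genes moved by 0.415 and 0.484. On chromosome 12 dimmer and brighter genes had 0.277 and 0.310 in tumour 2 and 0.307 and 0.247 in tumour 3. A change in part of the chromosome stays open: with genes in order of position, a stretch of 57 genes had -0.0609 on chromosome 15 in tumour 5 and a stretch of 45 genes had -0.0511 on chromosome 12 in tumour 2, with intervals from -0.268 to 0.449 and from -0.396 to 0.262. Myc lies on chromosome 15 of GRCm38.p6 but was raised in every tumour (at least 461.5, against at most 261.7 in thymocytes), so that an extra copy in tumours 2 and 5 could not be its only cause.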
